A study of Populus nigra with 461 samples.

How the data were processed

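RNA was sequenced from cambium and xylem, the wood-forming tissues, of black poplar (Populus nigra) trees aged 48 months. The 461 libraries come from 242 labelled genotypes of 11 labelled populations. Per the labels' protocols, the trees were planted in 2005 in 4 blocks and pruned 2 times, and the material was taken 4 years after the last pruning. Libraries were made by a stranded protocol after polyA selection, with single-end reads. A label holds the population, the genotype and a number. The number is 1 in 230 libraries, 3 in 229 and 2 in 2 libraries, and the labels do not say whether it stands for a planting block. There were 24 genotypes with 1 library, 217 with 2 and 1 with 3. The label DRA-13 of the Dranse library numbered 2 was counted as a genotype apart from DRA-013, and both libraries numbered 2 were kept under their labels. The series design text names biological replicates, so that libraries of 1 genotype were taken as separate trees of a clone.

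The deposited values are raw read counts for 41335 gene models with Potri identifiers of Populus trichocarpa, a related poplar species. Per the file headers, the authors counted reads with sam2pkm and removed reads with multiple best hits (equal AS and XS alignment scores). TopHat2 and Bowtie2 are named in the submitters' processing notes, with no version. The genome build was not given in the sources used here. The reads thus come from one species and the gene models from another, and reads of near-identical gene copies were removed before counting, so that counts of close paralogs such as the PAL and CesA pairs are uncertain. The headers also carry processing dates in 2016, which fall into 3 rounds, February with 77 libraries, March with 230 and June with 154. These rounds were treated as a technical batch. The round was unevenly spread over the numbers: of the libraries numbered 1, 57 were of the February, 84 of the March and 89 of the June round, against 20, 145 and 64 of those numbered 3.

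Totals of counted reads per library ranged from 6299270 to 42231293, with a median of 17420745, and 6 libraries lay below 0.5 times that median. Per the file headers, 90.0 to 96.1% of reads were mapped, with a median of 94.0%, and 2.98 to 3.57% of mapped reads had multiple best hits. Between 27751 and 32095 genes had reads in a library. The 10 most abundant genes took 2.26 to 7.71% of a library's counts. No column of the tables was left unused.

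Trees of a clone are not independent samples of a population. Counts of all libraries of a genotype were therefore summed, and the 242 sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr by population, quasi-likelihood F test, R 4.3.3), which kept 30411 genes. The populations were tested together, and each population was then set against the unweighted mean of the other 10. Fold changes are on the log2 scale, standard errors come from the same fit, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Genotypes within populations were tested over the 437 libraries of the 218 genotypes with at least 2 libraries. Number 3 was tested against number 1 with population as a covariate. Variance shares of log2 CPM (prior count 2) were estimated by the method of moments for population, genotype within population and residual. Clonal repeatability is the sum of the first 2 components over the total. The nearest library or genotype is the one with the highest Pearson r of log2 CPM centred per gene, tested with 100000 one-sided permutations of the names.

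The files do not pair gene identifiers with names, and 0 of the identifiers matched a table of Populus nigra genes (assembly ddPopNigr1.1). For this reason 18 gene lists that were to be drawn from gene descriptions could not be built. The other 6 lists, with 53 entries, hold published Populus trichocarpa names and identifiers. They cover monolignol biosynthesis, secondary wall cellulose, the xylan backbone, secondary wall regulators, wood zone markers and cambium regulators, and CesA8-B stands in 2 of them. Each list was tested in each population contrast, 66 pairs in all, with limma 3.58.1 camera at a preset correlation between genes of 0.01 and again with an estimated correlation. A list score per genotype is the mean over members of log2 CPM centred per gene, and populations were compared by two-sided tests with 100000 permutations of the population names. The median population share of each list was set beside 10000 random lists matched on mean expression in 20 bins. Members named are up to 4 per list with the smallest adjusted p in the test of all populations. Of genes outside the lists, 2 identifiers that were higher and 2 that were lower are given.

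Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were RLE size factors in edgeR, DESeq2's own tests (version 1.42.0) and limma-trend. Also tried were no low-count filter, a stricter one at a mean log2 CPM of 1, and libraries in place of sums with the number as a block. Each number was also taken alone, and shallow libraries or genotypes whose libraries were not nearest to each other were left out. For variance shares and profiles, removal of the first 5 principal components, a prior count of 0.5, the 1000 most variable genes and Spearman's rho were also tried. Chosen after seeing the data were fits with the processing round, fits within rounds, fits without the 2 libraries numbered 2 and the permutation tests of list scores. Population names were shuffled among genotypes in draws that with the real names make 32 splits. Genotype names were shuffled among libraries within populations, and numbers within genotypes, in draws that make 23.

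The steps were tested on simulated counts for the same 30411 genes. For Ticino against the other populations, 72.0% of genes changed 1.5-fold and 98.0% of those changed 2-fold were recovered, with 5 false calls. For Rhin, a smaller population, these shares were 66.0% and 84.0%, with 3 false calls. In the test of all populations 75.2% of 222 changed genes were recovered with 6 false calls. A simulated list shift of -0.40 was recovered, with 2 false list calls. Simulated genes were drawn independently of each other, so that false calls of genes or lists due to correlated genes are not measured. Simulated counts had the spread fitted to genes of their expression level. False calls from genes with a spread of their own are thus not measured either. In the real data, shuffled population names gave 361 to 811 calls in edgeR's test of all populations. Among genotypes, 90.0% of genes with a simulated SD of 0.5 were called, and between numbers 76.0% of genes changed 1.25-fold and 94.0% of those changed 1.5-fold. Simulated shares of 6% for population and 31% for repeatability came back as medians of 5.21% and 31.0%. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.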

Results

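Transcript levels were measured in 461 libraries from wood-forming tissue of black poplar trees to compare genotypes and ecotypes, the latter given in the labels as 11 populations. Ticino was represented by 54 genotypes, most of them with more than 1 library, Adour by 36 genotypes in 72 libraries, Loire by 34 in 64, Ramieres by 26 in 49, Kuhkopf by 19 in 34, ValAllier by 19 in 36 and Dranse by 17 in 31. Fewer genotypes came from Rhin (15 in 28), Paglia (13 in 26), Basento (5 in 9) and NL (4 in 8). Library totals lay between 6299270 and 42231293 counted reads. For pairs of trees of the same genotype, the chi-square of the counts per degree of freedom was 8.05 to 130.1, with a median of 30.8.

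Genes of monolignol biosynthesis, the pathway to the lignin monomers, differed among the populations in 20 of 22 measured members, and in 21 when adjusted over the list alone. The smallest adjusted p-values belonged to C4H2 (Potri.019G130700, cinnamate hydroxylase) at 1.94e-15, PAL1 (Potri.006G126800, phenylalanine ammonia-lyase, the entry step of the pathway) at 5.47e-15, CCoAOMT1 (Potri.009G099800, a methyltransferase of the pathway) at 6.62e-15 and PAL2 (Potri.008G038200) at 9.63e-15 in edgeR's test. Population accounted for 25.9% of the variance between trees for C4H2, 26% for PAL1, 20.4% for CCoAOMT1 and 22.1% for PAL2. The median over the list was 19.1% (bootstrap SD 3.73), against a median of 7.95% over 10000 random lists of the same expression level. Random lists hold unrelated genes and spread less than a list of correlated members would, so the percentiles below are descriptions and not tests. HCT6 (adjusted p = 0.0501) and CCR2 (adjusted p = 0.0868) did not pass the test over all genes.

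The other lists of the wood-forming tissue had smaller median population shares, from 3.15 to 6.62% (bootstrap SDs of 2.20 to 3.28). All 7 genes of secondary wall cellulose synthesis were called, 7 also when adjusted over the list alone, with CesA8-B, CesA7-A, CesA4 and CesA8-A, cellulose synthase subunits, at adjusted p-values of 1.63e-08, 4.93e-07, 4.17e-06 and 0.00413. Their list's median population share was 4.25%, percentile 10.3 among matched random lists. Of the xylan backbone enzymes 6 of 7 were called by both adjustments, led by GT47C with an adjusted p of 3.89e-14 and a population share of 18.8%, while the list's median was 3.15%, percentile 4.57. GT43B, GT43D and IRX10-1 followed at 2.54e-04, 7.89e-04 and 0.00208. Of the secondary wall regulators, 6 of 8 were called by both adjustments, among them the NAC genes WND1B (5.84e-07) and WND2B (2.56e-05) and the MYB genes MYB003 (5.86e-06) and MYB002 (3.92e-04), and the median share was 5.43% (percentile 34.2). Of 5 wood zone markers 3 were called by both adjustments: BFN1, a nuclease of dying xylem cells (1.66e-13), CesA8-B, and the cell division kinase CDC2 (0.00101). SUS6, the phloem marker, had an adjusted p of 0.309, and the list's median share was 3.74% (percentile 15.8). Of the cambium regulators, the receptor kinases PXYb (1.66e-06) and PXYa (0.00139) were called, 2 of 4 by both adjustments, while the homeobox genes WOX4b (0.111) and WOX4a (0.287) were not. The median share of this list was 6.62% (percentile 34.5).

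Over all genes, 21993 of 30411 (72.3%) differed among populations. The populations spanned at least 1 log2 unit for 5977 of these genes and at least 2 for 1223. With the libraries of a single processing round, 3192 genes were called in February, 16631 in March and 7121 in June.

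In Adour, the phenylpropanoid genes lay below the mean of the other populations. C4H2 fell by 0.52 on the log2 scale (SE 0.09, adjusted p = 7.52e-07), to a mean log2 CPM of 7.69 ± 0.35 (SD, n = 36 genotypes), PAL2 fell by 0.53 (SE 0.11), PAL1 fell by 0.50 (SE 0.13) and CCoAOMT1 fell by 0.34 (SE 0.07). Of the monolignol list 19 of 22 members were lower and 0 higher, with 19 lower and 1 higher when adjusted over the list alone. Among wall polysaccharide genes CesA8-B fell by 0.29 (SE 0.08), CesA7-A fell by 0.25, CesA4 fell by 0.23 and GT47C fell by 0.45 (SE 0.09). In these lists 3 of 7 cellulose genes and 2 of 7 xylan genes were lower by both adjustments. WND2B, WND1B and MYB002 were the 3 of 8 regulators that fell, by log2 changes of -0.28, -0.27 and -0.21, and 4 did so when adjusted over the list alone. BFN1 fell by 1.60 (SE 0.28) at a low mean log2 CPM of -2.09 ± 1.11 (SD, n = 36 genotypes). CDC2 was lower by a log2 change of -0.14 (SE 0.05), a difference that was 0.0123 with the libraries numbered 3 alone. Of the cambium regulators 0 of 4 were called. In all, 4367 genes were higher and 4409 lower than the mean of the other populations, with a median absolute log2 change of 0.26 and 933 genes at 2-fold or more. Thus 8776 of 30411 genes were called. The cellulose, xylan and regulator lists were not called in Adour by camera with the preset correlation (adjusted p = 0.183, 0.114 and 0.145). Without the library labelled Adour AST-010 number 2 and its counterpart in Dranse, 9348 genes were called.

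Ticino, with the most genotypes, had the largest number of called genes among the populations, a count that also depends on the number of genotypes. PAL1 fell by 0.74 (SE 0.11, adjusted p = 3.33e-09) to a mean log2 CPM of 5.94 ± 0.56 (SD, n = 54 genotypes), PAL2 fell by 0.68 (SE 0.09), C4H2 fell by 0.47 (SE 0.07) and CCoAOMT1 fell by 0.40 (SE 0.06). Lower expression was found for 17 of 22 monolignol genes, 18 when adjusted over the list alone, and higher expression for 0. The cellulose synthase genes CesA8-B, CesA7-A and CesA4 fell by 0.35, 0.31 and 0.30, and 4 of 7 genes of each polysaccharide list were lower by both adjustments. GT47C fell by 0.51 (SE 0.08), GT43B by a log2 change of -0.20 and IRX10-1 by -0.20. The regulators WND1B, MYB003 and WND2B changed by -0.30, -0.29 and -0.18, among 4 of 8 that were lower, or 6 lower and 1 higher when adjusted over the list alone. Cambium regulators went the other way. PXYb was 0.22 higher (SE 0.05, adjusted p = 3.28e-05), PXYa 0.20 higher (SE 0.04) and WOX4b 0.19 higher (SE 0.06), 3 of 4 members by both adjustments. The cell division marker CDC2 was 0.11 higher (SE 0.05), and BFN1 fell by 1.5 (SE 0.24). Counts over all genes were 7346 higher and 8142 lower, with a median absolute log2 change of 0.26 and 1281 genes at 2-fold or more. With 15488 of 30411 genes called, 4 called members of 7 or 8 do not by themselves set these lists apart. Camera with the preset correlation did not call the cellulose, xylan and regulator lists in Ticino (adjusted p = 0.232, 0.178 and 0.269). Outside the lists, the largest changes among genes with a mean log2 CPM of at least 1 that had the same direction with either number were Potri.004G176800 (2.82, SE 0.31) and Potri.013G026000 (1.30, SE 0.23) on the higher side and Potri.004G184000 (-2.29, SE 0.30) and Potri.016G006100 (-2.24, SE 0.37) on the lower side. The last of these is a gene that was on, at or above 2 CPM, in 26% of the Ticino libraries and near absent in most others there, so that its change reflects the share of trees with the transcript. The files do not pair these identifiers with names.

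In Loire, most monolignol genes and some genes of the wall polysaccharides lay above the mean of the other populations. PAL1 was 0.54 higher (SE 0.12, adjusted p = 5.33e-04), with a mean log2 CPM of 7.05 ± 0.67 (SD, n = 34 genotypes), PAL2 0.45 higher (SE 0.10), C4H2 0.41 higher (SE 0.08) and CCoAOMT1 0.35 higher (SE 0.07). Of the 22 monolignol genes 17 were higher, or 19 when adjusted over the list alone, and 0 were lower. CesA7-A (0.28), CesA8-B (0.26) and CesA4 (0.23) were the 3 of 7 cellulose genes that rose. GT47C (0.45), IRX10-1 (0.23) and GT43D (0.16) were among 4 of 7 xylan genes that rose, or 5 when adjusted over the list alone. MYB003 (0.29) and WND2B (0.19) were among 3 of 8 regulators that rose by both adjustments, and BFN1 was 0.90 higher (SE 0.24). Of the cambium regulators 0 of 4 were called. Altogether 2925 genes were higher and 1824 lower, with a median absolute log2 change of 0.30. The count was 2352 with the libraries numbered 3 alone and 1409 without the genotypes whose libraries were not nearest to each other.

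In Ramieres, some genes of cellulose synthesis were lower. CesA8-B fell by 0.28 (SE 0.09, adjusted p = 0.0289) to a mean log2 CPM of 9.93 ± 0.53 (SD, n = 26 genotypes), and CesA8-A fell by 0.24 (SE 0.08). These were among 3 of 7 cellulose genes called, or 6 when adjusted over the list alone. MYB002 fell by 0.35 (SE 0.08), GT43D fell by 0.21 (SE 0.06), PXYb fell by 0.24 (SE 0.06) and C4H2 fell by 0.29 (SE 0.10). These were the only members called of 8 regulators, 7 xylan, 4 cambium and 22 monolignol genes, against 5 lower and 1 higher regulators, 1 xylan, 1 cambium and 0 monolignol genes when adjusted over the list alone. CDC2 was 0.20 higher (SE 0.06). Over all genes 2265 were higher and 1580 lower, and 1372 were called with the libraries numbered 3 alone.

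Within the February, March and June rounds, 91.0, 99.98 and 99.1% of the genes called in Adour had the same direction as in all libraries. These shares were 96.4, 99.9 and 94.1% in Ticino, 88.8, 99.7 and 99.6% in Loire and 83.8, 99.9 and 99.5% in Ramieres. In Dranse, Kuhkopf, Paglia, Rhin and ValAllier they lay between 85.3% (Dranse in February) and 99.9% (Kuhkopf in March). For Basento they were 98.8% in March and 81% in June, and for NL 100% in March, the other rounds holding 1 library or 0. The libraries of each round were among those that called these genes, so that high shares are in part fixed in advance. No such shares were computed with shuffled names.

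The remaining populations, each with fewer genotypes and so less power, had fewer genes called against the mean of the others. Few of these genes were on the lists. The monolignol list had 1 higher gene in each of Dranse and Paglia (1 and 3 when adjusted over the list alone) and 0 called genes in Kuhkopf, ValAllier, Rhin, Basento and NL, and of the other lists 0 genes were called in these 7 populations over all genes tested. In NL, with 4 genotypes, 6 monolignol and 6 cellulose genes were higher when adjusted over the list alone. CesA8-B was 0.57 higher there (SE 0.20) and MYB002 0.60 higher (SE 0.17), with adjusted p-values of 0.167 and 0.0813 over all genes. The counts of higher and lower genes were 941 and 499 in Paglia, 835 and 585 in Kuhkopf, 867 and 479 in ValAllier, 460 and 269 in Dranse, 422 and 114 in Basento, 259 and 112 in Rhin and 147 and 35 in NL. Median absolute log2 changes of called genes were 1.71 in NL and 1.28 in Basento, against 0.26 in Ticino and Adour, which had more genotypes. The share of higher genes among calls depended on the test, at 78.7% by edgeR, 45.2% by limma-trend and 53.3% by DESeq2 in Basento, 80.8, 52 and 39% in NL, 69.8, 43.5 and 45.2% in Rhin, 63.1, 45.4 and 48.7% in Dranse and 58.8, 40.2 and 52.2% in Kuhkopf.

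**Figure D1:**
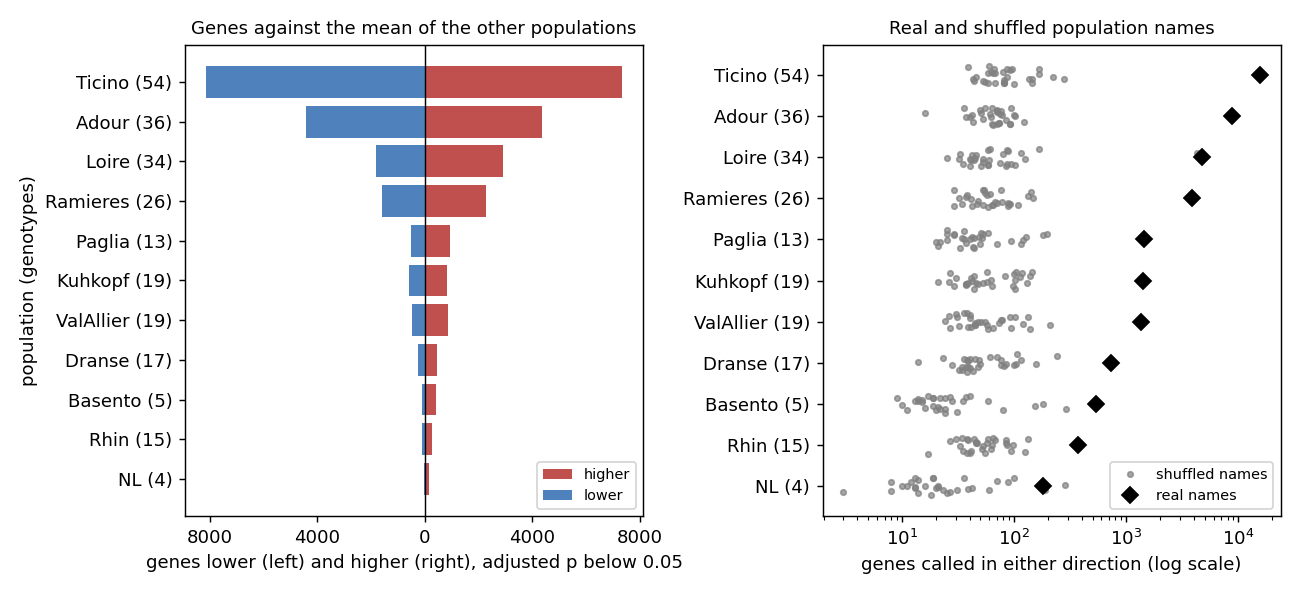
Left, genes lower (blue) and higher (red) in each population than the mean of the other 10, at an adjusted p below 0.05 in edgeR's test, with the number of genotypes in brackets. Right, the number of genes called in either direction with the real population names (diamonds) and with shuffled names (grey points) on a log scale; Ticino had 15488 and Adour 8776 called genes, and in Loire 1 grey point at 4276 lies behind the diamond at 4749.

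**Figure D2:**
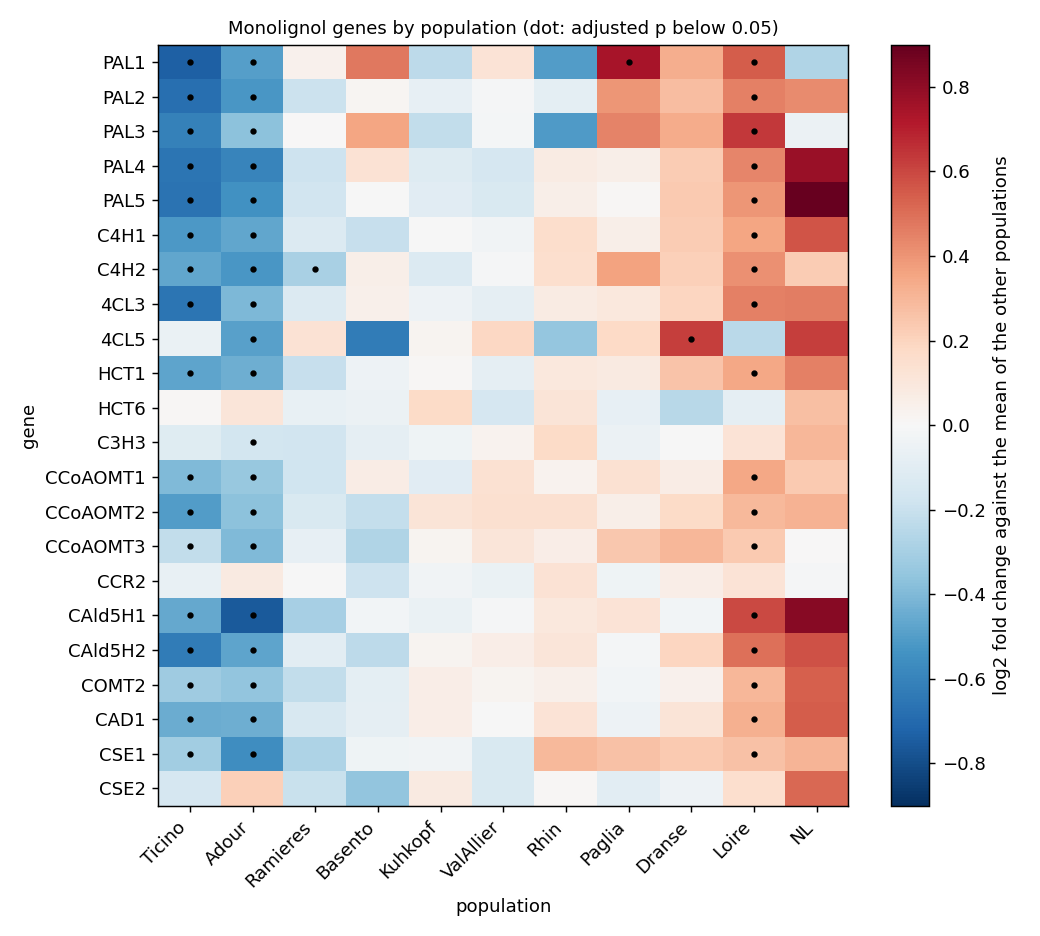
Log2 fold change of the 22 monolignol genes (lines) in each population (columns) against the mean of the other populations, with dots where the adjusted p of edgeR's test lay below 0.05. Of these genes 19 were lower in Adour, 17 lower in Ticino and 17 higher in Loire.

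The list scores gave the size of these shifts per genotype. The monolignol score was lower in Adour than the mean of the other populations by a log2 difference of -0.36, with 32 of 36 genotypes on that side (p = 3e-05, permutation test), and in Ticino by -0.40, with 48 of 54 genotypes (p = 1e-05, the smallest the permutations can give). In Loire it was higher by 0.29, with 23 of 34 genotypes on that side (p = 6.3e-04). These 3 differences had adjusted p-values of 4e-04, 2.2e-04 and 0.00693 over 66 pairs of a list and a population. Within the February, March and June rounds the monolignol difference was -0.08, -0.44 and -0.27 in Adour, -0.38, -0.31 and -0.48 in Ticino and 0.11, 0.36 and 0.29 in Loire. In each round all populations present weighed alike in the mean of the others. Basento and NL had 1 genotype each in February, so that 1 genotype can move the February differences of all other populations. The cellulose score was lower in Ramieres by -0.23 (adjusted p = 0.0294, 20 of 26 genotypes, permutation test), with 0.08 in February (6 genotypes), -0.21 in March and -0.26 in June. The 1 Basento genotype of February, at -1.26, raised the February differences of the other populations. The February sign in Ramieres may therefore rest on it. The xylan score was lower in Ticino by -0.16 and higher in Loire by 0.19 (adjusted p = 0.0342 for both), and by round it differed by -0.09, -0.06 and -0.34 in Ticino and by 0.10, 0.20 and 0.19 in Loire. The cambium regulator score was higher in Ticino by 0.16, in 43 of 54 genotypes (adjusted p = 4e-04), with 0.23, 0.21 and 0.10 in the 3 rounds. The wood zone score differed by -0.38 in Adour and -0.31 in Ticino (adjusted p = 2.2e-04 for both) and by 0.20 in Loire (adjusted p = 0.0386), but BFN1, a gene of low counts, carried most of it. The median changes of its members were -0.14, -0.10 and 0.02, and CDC2 went the other way in Ticino. By round the score differences were -0.13, -0.41 and -0.31 in Adour, -0.42, -0.28 and -0.19 in Ticino and 0.08, 0.20 and 0.11 in Loire. The regulator score passed in 0 populations, with -0.12 in Ticino at an adjusted p of 0.107 and an unadjusted p of 0.0228.

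**Figure D3:**
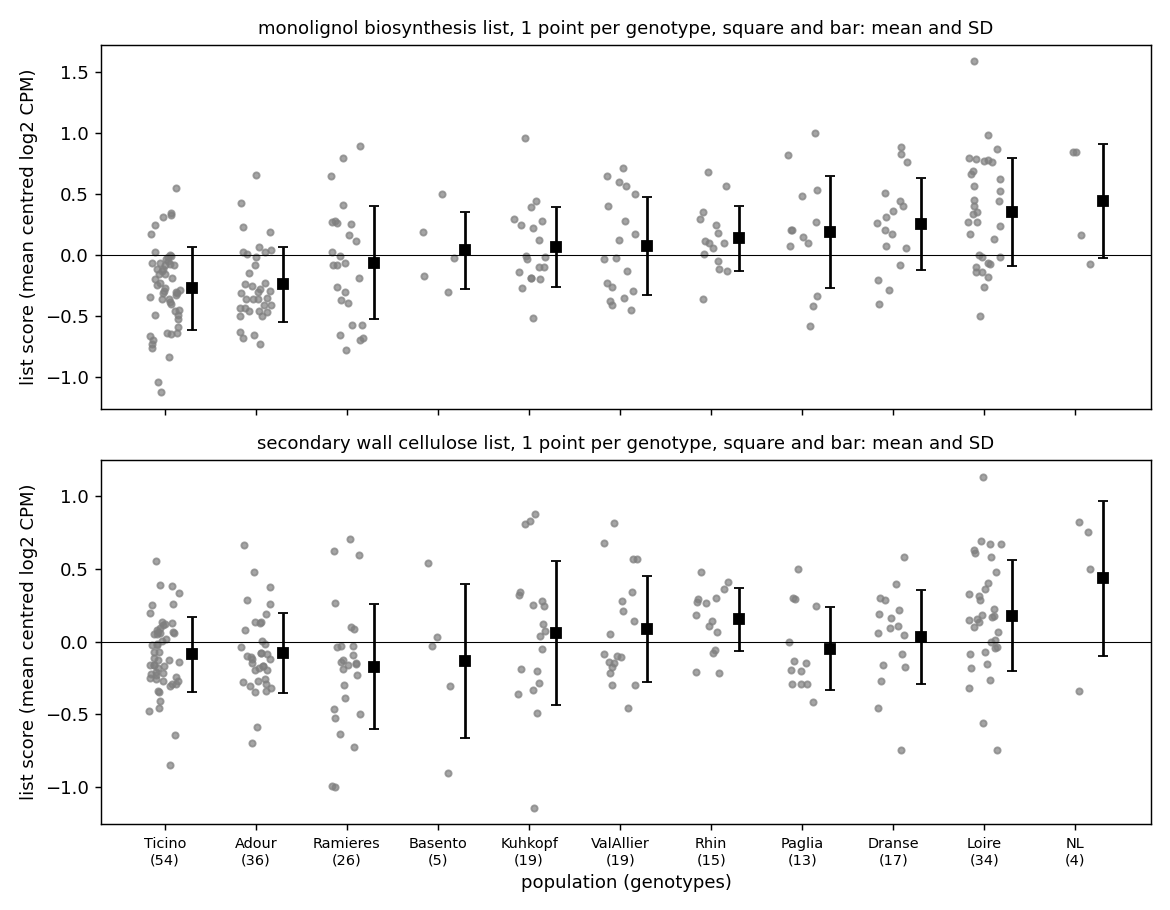
Score of the monolignol list (top) and of the secondary wall cellulose list (bottom) in log2 CPM centred per gene, with 1 point per genotype and the mean and SD of each population as a square with a bar. Mean monolignol scores were -0.24 in Adour and 0.35 in Loire.

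Against other genes, camera with a preset correlation called 13 of 66 pairs of a list and a population. The monolignol list was higher in Loire (adjusted p = 6.37e-11), NL (2.59e-06) and Dranse (5.59e-04) and lower in Adour (3.12e-10), Ticino (4.76e-09) and Ramieres (3.48e-04). The adjusted p was 0.705 in Loire, Adour and Ticino, 0.714 in NL and 0.830 in Dranse and Ramieres with an estimated correlation. The cellulose and xylan lists were called as higher in Loire (0.0275 and 0.00280) and NL (8.56e-05 and 0.00285) and lower in Ramieres (4.86e-04 and 0.0110), and the regulator list as higher in NL (0.00133). For these 7 pairs the adjusted p lay between 0.705 and 0.830 with an estimated correlation, so that 0 of 66 pairs were called, while 3 pairs had an unadjusted p under 0.05. Part of the calls with the preset correlation depended on the libraries used, with 8 calls in the libraries numbered 3 alone and 18 in those numbered 1 alone. The monolignol list in Dranse turned to lower in the libraries numbered 1 alone (adjusted p = 0.120). In those numbered 3 alone the monolignol list was not called in NL (0.104) and Ramieres (0.0947), the cellulose list not in Loire (0.0947), NL (0.0770) and Ramieres (0.0575), and the xylan list not in NL (0.168) and Ramieres (0.0697). The cellulose list was not called in Loire with the libraries numbered 1 alone either (0.0587). Other lists were called only with the libraries of 1 number. In Dranse the cellulose list was lower in those numbered 1 alone (1.26e-04) and higher in those numbered 3 alone (0.0288), and the xylan (0.00253) and regulator (0.0320) lists were lower in those numbered 1 alone. Those numbered 1 alone also gave lower monolignol (2.6e-05), cellulose (2.13e-04) and xylan (0.0111) lists in Basento and lower wood zone markers in Adour (0.0174), and those numbered 3 alone a lower monolignol list in ValAllier (0.0396). Wood zone markers and cambium regulators were called in 0 populations by camera with all libraries.

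Trees of the same genotype shared a part of the variance of the listed genes, at most 39.1% in the median of a list. Genotypes within populations differed for 21 of 22 monolignol genes, 7 of 7 cellulose genes, 7 of 7 xylan genes and 7 of 8 secondary wall regulators, but for 2 of 5 wood zone markers and 2 of 4 cambium regulators. Clonal repeatability, the share of the variance held in common by trees of a genotype, was 54.8% for PAL1, 51.9% for C4H2, 44.1% for PAL2 and 34.4% for CCoAOMT1. It was 49.9% for BFN1, 36.6% for MYB003, 32% for GT47C and 30.2% for CesA8-B, against 1.77% for SUS6, 6.43% for WOX4a and 9.29% for CDC2. The list medians were 39.1% for monolignol genes, 31.5% for xylan, 25.7% for cellulose, 20.8% for regulators, 19.3% for cambium regulators and 9.29% for wood zone markers. Over all genes 25405 of 30411 (83.5%) differed among genotypes within populations, and 25493 by limma-trend with the processing round and the number as covariates. Median repeatability was 31.4% (quartiles 19.5 and 47.6%, bootstrap SD 1.66), and it exceeded 50% for 6826 genes. With genotype names shuffled within each population 20 times, which keeps the population part of repeatability, the median was 8.42 to 10.5%. Population held a median of 6.19% of the variance (quartiles 2.79 and 11.2%, bootstrap SD 0.760) and over 50% for 24 genes, and for 3242 genes its share was larger than that of genotype within population. The median repeatability was 44.8% without the genotypes whose libraries were not nearest to each other, a selection on the same values.

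**Figure D4:**
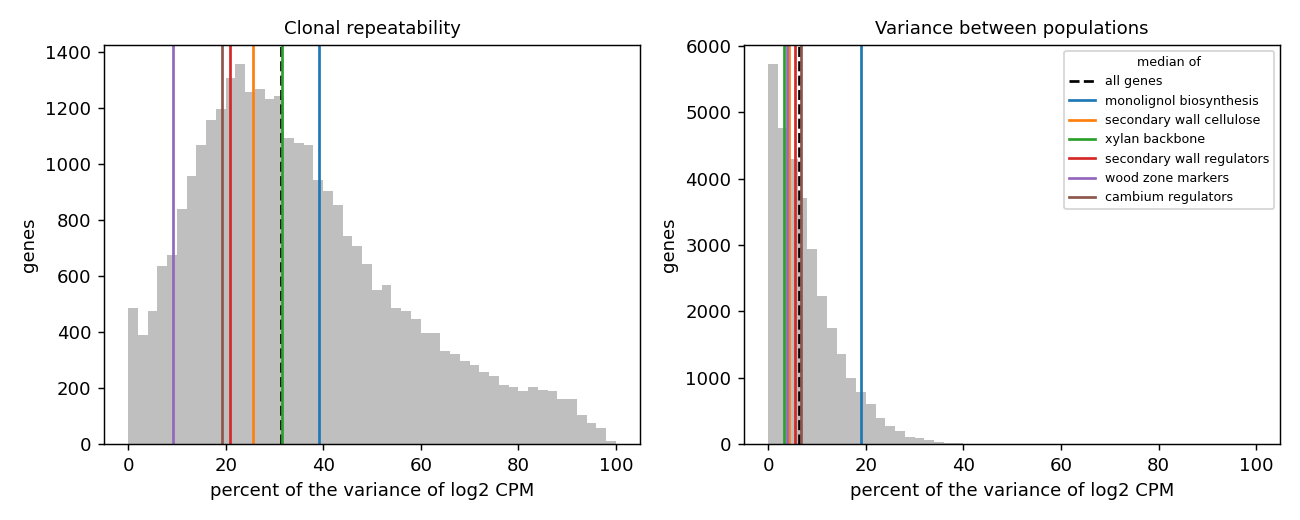
Number of genes by clonal repeatability (left) and by the share of variance between populations (right), in percent of the variance of log2 CPM, with the median of all genes (dashed) and of each list (lines). The monolignol list median lies at 39.1% on the left and 19.1% on the right, against 31.4 and 6.19% for all genes.

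Whole profiles grouped trees by genotype and genotypes by population. For 305 of 437 libraries the nearest library was of the same genotype, against a mean of 0.961 with permuted names (p = 1e-05, permutation test, the smallest the permutations can give), and this held for 432 libraries after the first 5 principal components were removed, for 360 with the 1000 most variable genes and for 214 with Spearman's rho. The nearest other genotype was of the same population for 164 of the genotypes, against 30.1 with permuted names (p = 1e-05, permutation test), and for 149 with Spearman's rho. By population, these were 51 of 54 in Ticino, 31 of 36 in Adour, 24 of 34 in Loire, 15 of 26 in Ramieres, 14 of 19 in Kuhkopf, 10 of 13 in Paglia, 8 of 19 in ValAllier, 6 of 17 in Dranse, 2 of 5 in Basento, 2 of 15 in Rhin and 1 of 4 in NL.

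Few listed genes were called between the trees numbered 1 and 3. Of the lists, only the regulator MYB020 passed the test (adjusted p = 0.00217, lower in number 3), which is named here after its value was seen, and 0 of 22 monolignol, 7 cellulose, 7 xylan, 5 wood zone and 4 cambium genes did. C4H2, PAL1, PAL2 and CCoAOMT1 had adjusted p-values of 0.988, 0.821, 0.705 and 0.209. These values of listed genes come from edgeR's test, which does not pair the trees of a genotype. The spread between genotypes thus stays in its error. In all, 1796 of 30411 genes differed, 1214 higher and 582 lower in number 3. Their median absolute log2 change was 0.30, and 26 genes changed 2-fold or more. At this share, few calls on short lists do not set the wood genes apart. With limma-trend on the differences within genotypes 2386 genes differed, 1175 higher and 1211 lower, so that the excess of higher genes depended on the test. With the processing round as a covariate 1226 genes differed. These tests look for a shift common to all populations and can miss opposite ones. In Dranse, named after its values were seen, the monolignol score differed from the other populations by -0.07 with number 1 alone and by 0.48 with number 3 alone.

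**Figure D5:**
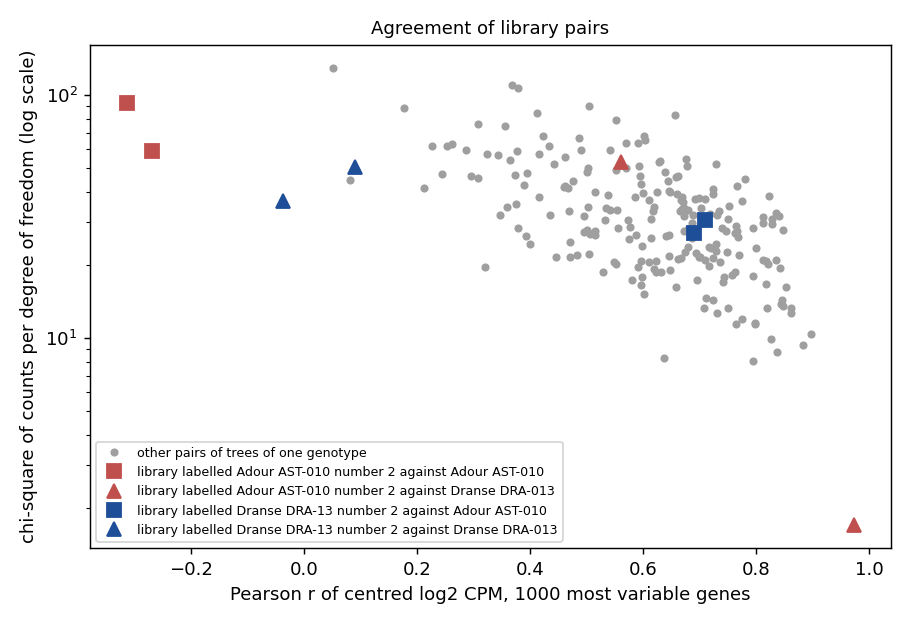
Pearson r of centred log2 CPM over the 1000 most variable genes against the chi-square of counts per degree of freedom (log scale) for the pairs of trees of a genotype (grey), and for the libraries labelled Adour AST-010 number 2 (red) and Dranse DRA-13 number 2 (blue) against the trees of both genotypes. The red triangle at r = 0.973 and 1.69 is the pair of the library labelled Adour AST-010 number 2 and the tree numbered 1 of Dranse DRA-013.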

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

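The fits with the processing round, within rounds, without the 2 libraries numbered 2 and the permutation test of list scores were chosen after the data were seen, and the other alternatives before. Of 201 alternative values of the main results 139 stayed within 1.5 times the main count or within its spread and 62 moved. Of 668 alternative values of named genes and lists 603 kept their direction and their side of the threshold, 61 kept the direction but were no longer called, 2 became called and 2 turned. The monolignol list in Dranse turned to lower, with an adjusted p of 0.120, in the libraries numbered 1 alone, against higher with 2.38e-13 in those numbered 3 alone, and the log2 change of CDC2 in Adour was 0.0123 in those numbered 3 alone and -0.27 in those numbered 1 alone. The cause was not tested for the values below unless stated.

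The numbers 1 and 3 were not taken to pair the samples, since not every pair of populations deviated together. Over 55 pairs, the deviations of same-numbered libraries correlated with r from -0.25 to 0.60, with a median of 0.145 and 33 pairs over 0.1, so that some effect of the number is shared. With libraries in place of genotype sums and the number as a replicate block, the counts were 1403 in Basento, 3403 in Dranse, 3146 in Kuhkopf, 8290 in Loire, 1108 in NL, 3448 in Paglia, 6864 in Ramieres, 1055 in Rhin and 3208 in ValAllier. This alternative takes trees of a clone as independent, which raises the number of units tested. With the processing round as a further covariate of the replicate block they were 1392, 3233, 3063, 7824, 982, 3177, 6811, 1088 and 3211. The counts for all populations together and for Adour and Ticino stayed within 1.5 times.

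With 1 library per genotype, which lowers the depth and the number of trees, counts lay between 5415 and 8036 in Adour, 125 and 473 in Basento, 739 and 1676 in Dranse, 815 and 1184 in Kuhkopf, 2352 and 3672 in Loire, 90 and 141 in NL, 669 and 1367 in Paglia, 1372 and 2714 in Ramieres, 207 and 226 in Rhin and 781 and 785 in ValAllier, and list calls between 8 and 18. Without genotypes whose libraries were not nearest to each other, which leaves fewer genotypes, they were 323 in Basento, 1117 in Dranse, 469 in Kuhkopf, 1409 in Loire, 234 in Paglia, 2351 in Ramieres, 234 in Rhin and 444 in ValAllier. The stricter filter, which tests fewer genes, gave 248 in Basento, 262 in Dranse, 632 in Kuhkopf, 57 in NL, 581 in Paglia, 111 in Rhin, 602 in ValAllier and 1044 between the numbers. Limma-trend gave 299 in Basento, 414 in Dranse, 102 in NL and 237 in Rhin.

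Fewer libraries also stand behind the 3192 genes called among populations in the February round and the 7121 in the June round. An estimated correlation left 0 list calls. Median repeatability was 44.8% and the population share 7.25% without genotypes whose libraries were not nearest to each other, and 36.2 and 3.45% with 5 principal components removed. The latter also lowered the median population share of the monolignol list to 7.98%, of the cellulose list to 0.974%, of the regulators to 2.92%, of the wood zone markers to 1.04% and of the cambium regulators to 2.57%, while that of the xylan list was 3.93% in place of 3.15%. DESeq2, RLE size factors in edgeR, no filter and leaving out the 6 shallowest libraries or the 2 libraries numbered 2 kept every total count of populations and contrasts within 1.5 times. DESeq2 moved the higher and lower genes from 147 and 35 to 67 and 105 in NL, from 422 and 114 to 234 and 205 in Basento and from 259 and 112 to 175 and 212 in Rhin.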

Other observations

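The tests of tissue share, exchanged labels, mixed RNA and on/off genes, and all shuffles of names, were chosen after the results were seen. Those of processing round and library depth were chosen after the monolignol differences were seen, with their bounds set before their own values were. Because the files do not pair most identifiers with names, gene groups beyond the 6 lists were not analysed here.

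Transcripts of 30 genes were near absent in some trees and present in others. For each of them, at least 20 libraries were off (below 0.2 CPM), at least 20 were on (at or above 2 CPM) and at most 23 lay between. The median level when on was 6.20 CPM over these genes. Leaving out the 2 libraries numbered 2, on and off calls differed in 2 of 6302 comparisons between trees of the same genotype, against 26.8% of comparisons in 104893 pairs of different genotypes, and 21 of the latter pairs had 0 discordant genes. A level of 2 CPM equals 12.6 reads in the shallowest library. Of these genes 0 had neighbouring identifiers.

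The monolignol and cellulose lists did not shift by the same amount in all populations. The monolignol score minus the cellulose score was lower in Ticino by -0.26, in 51 of 54 genotypes (p = 1e-05, permutation test, the smallest the permutations can give), and in Adour by -0.24, in 32 of 36 genotypes (p = 2e-05). It was higher in Paglia by 0.21 (9 of 13 genotypes, p = 0.0133), in Dranse by 0.19 (13 of 17, p = 0.0115) and in Loire by 0.14 (22 of 34, p = 0.0144). In NL the difference was -0.05 (p = 0.755, permutation test). Within the February, March and June rounds the difference was -0.39, -0.26 and -0.12 in Ticino, -0.20, -0.31 and -0.20 in Adour and -0.08 (6 genotypes), 0.22 and 0.12 in Loire. In the same rounds it was -0.05 (5 genotypes), 0.10 and 0.29 in Paglia and -0.05 (3 genotypes), 0.28 and 0.15 in Dranse. In February Basento had 1 genotype, at 0.85, which counted as a full population in the mean of the others. It lowered the other February values, so that the negative signs in Loire, Paglia and Dranse may rest on it. In Paglia it was 0.11 with the libraries numbered 1 alone and 0.26 with those numbered 3 alone.

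The first pattern weighed is that monolignol genes were lower in Adour and Ticino and higher in Loire. A smaller or larger share of tissue with secondary walls in the sampled material would move the cellulose list as far as the monolignol list, if both depend on it alike, which was assumed. The difference between the lists argues against this as the whole cause in Ticino and Adour (p = 1e-05 and 2e-05, permutation test). In Loire the values are weaker (p = 0.0144, not adjusted over the 11 populations). The 3 populations were picked by their monolignol scores, which pushes the difference toward the same sign. With the processing round of the count files as a covariate, at least 95.4% of each of the 3 differences was left, and with library depth and share of mapped reads at least 97.0%. The cambium regulator score (0.08, 0.16 and -0.08 in Adour, Ticino and Loire) and BFN1 (-1.60, -1.5 and 0.90, at low counts) moved in the direction that such a change would give, as did CDC2 in Ticino (0.11) but not in Adour (-0.14, or 0.0123 with the libraries numbered 3 alone), so that a part of the pattern stays open to it. Trees at different stages of lignification at harvest, or inherited differences in the regulation of the pathway, may underlie the pattern, and neither was tested.

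The second pattern is that the 2 libraries numbered 2 resemble each other's genotype. The library labelled Adour AST-010 number 2 correlated with Dranse DRA-013 number 1 at r = 0.973 and with the other AST-010 trees at -0.27 and -0.31, and the library labelled Dranse DRA-13 number 2 correlated with the AST-010 trees at 0.69 and 0.71. If the labels of the 2 libraries were exchanged, on/off calls should match the other's genotype: 0 of 118 calls differed from it, against 28 of 118 from the labelled one. These calls repeat the 30 on/off genes over library pairs, with 7 discordant genes in each pair with the labelled genotype, and are not independent. RNA of both genotypes mixed in each library is argued against by genes on in the labelled genotype and off in the library, 3 in the first library and 4 in the second. Those are part of the same discordant calls. An exchange of the labels is consistent with these values, which rests on reading DRA-13 as DRA-013, and the chi-square of 1.69 per degree of freedom between the first library and Dranse DRA-013 number 1, against 8.05 or more in other pairs of a genotype, leaves open that these are 2 libraries of 1 tree.

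The third pattern is the genes that are on in some genotypes and off in others. Too few reads in shallow libraries would make trees of a genotype disagree about as often as other trees, but 0.0317% of their calls differed when the 2 libraries numbered 2 were left out. Alleles that differ too much from the Populus trichocarpa gene models for reads to map, reads removed because they also fit a near-identical copy, genes missing from some genotypes and genes silent in some may all give such calls, and these were not tested.

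Shuffled names gave fewer genes than the real ones in most comparisons. Among populations 21993 genes were called, against at most 811 in the other 31 of 32 splits (1 split as large), so that chance can be excluded, but the splits still called at least 361 genes by edgeR and at most 29 by limma-trend, where 0 are real. The real names also gave the most genes for Ticino, with 15488 against a highest other split of 276, Adour (8776 against 123) and Ramieres (3845 against 147). So they did for Paglia (1440 against 196), Kuhkopf (1420 against 143), ValAllier (1346 against 209), Basento (536 against 289) and Rhin (371 against 134), with 1 of 32 splits as large in each. The same held for Dranse (1 of 32 splits as large), with 729 genes, 3.01 times the highest other split. A share of 1 in 32 is the smallest these splits can give. That share was not adjusted over the 11 populations, so that it speaks against chance for each of them only at that level. For Loire chance is not firmly excluded. The real names gave 4749 genes there (1 of 32 splits as large), but 1 other split called nearly as many, 4276. The reason for this split was not tested. Its count exceeds the real ones of Ramieres and the smaller contrasts, so that 31 draws do not firmly exclude chance for those either. The real counts of Ticino and Adour lay well above it. Without the 6 shallowest libraries 3917 genes were called in Loire, and no shuffles were run for that fit. For NL, with 182 genes, 3 of 32 splits gave as many and the highest other gave 287, so that chance cannot be excluded. It cannot be excluded for the 13 list calls either, since 21 of 32 splits gave as many, up to 26. Genotypes within populations gave 25405 genes against at most 2318, and the numbers 1796 against at most 27, with 1 of 23 splits as large in each, so that chance can be excluded.

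Dixon's test for a sample far from the others was run in 18 groups of 4 to 10 values and passed its critical value in 0.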
